A study of Homo sapiens with 6 samples.

How the data were processed

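miCLIP libraries of poly(A)-selected RNA from HCT116 cells were compared in 3 genotypes, WT, METTL5 knockout and ZCCHC4 knockout, with 2 libraries each. Genotypes were taken from the genotype labels. The submitters' processing notes name BWA 0.7.17, edgeR and the genome builds GRCh38 and hg38. The site caller, the tag collapsing and the edgeR version are not given in the sources used here.

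The site lists deposited by the authors give, per library, the position and strand of each called site, its tag coverage and its count of C-to-T tags, as whole-number counts that were not normalized. The values show at least 4 tags of coverage, at least 2 C-to-T tags and a C-to-T share between 1% and 50% at every site, and a DRACH 5-mer at all of them. A site missing from a list may be unmethylated or below these limits, so absence was read as not called. The tables deposited by the authors give, per window of a transcript, a log2 fold change, a log2 abundance, a p-value and an adjusted p-value, per the file headers. Windows start at steps of 40 nt, and there are 5184 on 529 transcripts, 3 of them RefSeq rRNA records. The adjusted values equal a Benjamini-Hochberg adjustment of the deposited p-values over all windows.

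The tables do not state the direction of the fold change, and it was worked out from the values. The p-values of windows with few tags match those of an exact test of small whole numbers at a dispersion of 9.77e-05, which gives back the 2 group counts. Both tables share the WT libraries. In 470 windows read in both tables, the WT count was the same in 93.8% if a positive value means higher in WT, and in 33.8% if it means higher in the knockout. Positive values were therefore read as higher in WT. Tested on 500 simulated windows, the reading gave the right count in 100% of those it could read. Their p-values were made with the same model and dispersion, so this checks the reading back alone. It does not check that the deposited p-values follow the model. Windows with more tags did not match this dispersion. The 18S and 28S records repeat sequence of the 45S record and come from the same libraries, so they were not read as independent. How tags were assigned between the records is not known. At nearly the same place in 28S, the authors' deposited log2 abundance was 11.74 in the 45S record (window 12081) and 9.39 in the 28S record (window 4161).

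Genes were named from the RefSeq table of GRCh38.p14 by position: the only protein-coding gene at a position, otherwise the only other gene. The table has no strand, exons or scaffolds, so the planned shares of UTR, coding sequence and introns were replaced by the place of a site along the gene interval, read in the direction of the site's strand. Of 24979 positions, 94.2% lay in 1 gene, 5.28% in several and 0.5% outside genes. At 71 positions a gene was named by setting aside an antisense RNA, a rule added after the data had been examined, and it names the MALAT1 sites. Mitochondrial sites share sequence with nuclear copies such as MTRNR2L1, so their coverage is uncertain. Sites close to each other share tags.

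The overlap of the tables' windows was set beside simulated unchanged groups with lists of the same length, a comparison added after the data had been examined. Site lists were compared by identical chromosome, position and strand. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333. Per-library counts for the tables are not used here, so the planned count test was replaced by the authors' values. A test of tag coverage was added after the data had been examined. Sites called in all 4 libraries of a comparison were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood) in R 4.3.3, with DESeq2 1.42.0 as an alternative and camera and fry from limma 3.58.1 with a preset correlation of 0.01 for gene lists of at least 3 genes, 1 site per gene. Standard errors were taken from the log2 fold change and the F statistic. Requiring a call in WT replicate 1, the least covered library, favours sites that were high there. On simulated counts with 40 sites changed 4-fold, the test recovered 97.5% with 2 false calls among 372 sites for METTL5. For ZCCHC4 it recovered 100% with 0 false calls among 246 sites. The simulation used a common dispersion, and the changes printed below for sites that passed were smaller than 4-fold. It therefore does not show how the test performs at those sizes. Python 3.11.15 with scipy 1.17.1 was used for the rest.

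The 16 gene lists, the tests and the alternatives in the closing section, apart from those named there as added, were set before the data were examined. So was the rule for named sites: sites on rRNA; METTL5, ZCCHC4, TRMT112, METTL3 and METTL14; the 10 most covered sites called in all 6 libraries and the 10 called in both WT libraries and in neither library of a knockout; members of the gene lists past an adjusted p of 0.05, up to 4 a list; and of differential sites past 0.05 the 12 with the largest change in each direction, or, where fewer than 5 passed in a direction, the 8 with the smallest p. Of the rRNA windows, those that stood apart are printed and the others summarised, and of unnamed transcripts at most 2 identifiers per direction. The same rule was applied to the added coverage test, except that in the METTL5 knockout only the sites that passed are printed. ACTG1 and EEF2, the most covered nuclear sites apart from MTRNR2L1, the genes with the most positions, and MCM5 were chosen after their values were seen.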

Results

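N6-methyladenosine (m6A) was mapped by miCLIP, in which an anti-m6A antibody is crosslinked to RNA and leaves C-to-T changes next to the modified adenosine in the sequenced tags. The RNA was poly(A)-selected RNA of HCT116 cells, a human colorectal carcinoma line. The 6 libraries fall into 3 genotypes of 2 libraries each: wild type (WT), METTL5 knockout and ZCCHC4 knockout. METTL5 is named in the series title as the 18S rRNA m6A methyltransferase, and ZCCHC4 is known as a 28S rRNA m6A methyltransferase. The stated purpose was to look for methylation that depends on either enzyme. Each library has a list of called sites with the tag coverage and the number of C-to-T tags, and 2 tables by the authors compare each knockout with WT in windows along transcripts. The summed tag coverage over called sites was 54583 and 539392 in the WT libraries, 365655 and 238655 in the METTL5 knockout libraries, and 129172 and 178003 in the ZCCHC4 knockout libraries, which is not the depth of a library, since it counts tags at called sites alone. Nothing in the labels says that the libraries of a genotype came from separate cultures, so p-values measure the spread between libraries, which may be technical.

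The first question was whether signal on 18S rRNA depends on METTL5. The 3' end of 18S rRNA had lower signal in the METTL5 knockout than in WT. In the authors' deposited table the window starting at nt 5481 of the 45S pre-rRNA record (RNA45SN1, chromosome 21, 8433222 to 8446572, GRCh38), which is nt 1827 of 18S, had a log2 WT over knockout of 3.47, an 11.1-fold difference. The windows before it, at 5441 and 5401, had log2 values of 2.90 and 2.46 in the authors' deposited table. The 148 other windows of this record had a median log2 of -0.21, and the highest of them reached 0.15. In the authors' deposited table for the ZCCHC4 knockout the same 3 windows had log2 values of -0.38, -0.38 and -0.35. The separate 18S record (RNA18SN1, chromosome 21, 8436876 to 8438744) repeats this sequence, and its windows at 1761 and 1801 had log2 values of 2.23 and 2.42 in the authors' deposited table, where the p-values read back as 6 tags in WT against 1 in the knockout. By the authors' edgeR test, the window at 5481 had the smallest p-value of all 5184 windows, 0.0017, but its adjusted p was 1, as in every row of the authors' deposited table. Adjusted over the 188 rRNA windows alone, its p by the authors' edgeR test became 0.319.

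The corresponding question for ZCCHC4 concerned 28S rRNA. A block of 28S rRNA had lower signal in the ZCCHC4 knockout than in WT. In the authors' deposited table the window at nt 12081 of the 45S record, which is nt 4157 of 28S, had a log2 WT over knockout of 3.43, a 10.8-fold difference. Its neighbours at 12041, 12121 and 12161 had log2 values of 2.67, 3.26 and 2.72 in the authors' deposited table. The 147 other windows of the record had a median of -0.18 and a highest value of 0.44. In the authors' deposited table for the METTL5 knockout these 4 windows had log2 values of -0.18, -0.18, -0.18 and -0.19 in the order of position. The separate 28S record (RNA28SN1, chromosome 21, 8441146 to 8446211) had log2 values of 2.59, 3.22, 3.09 and 2.37 at 4121, 4161, 4201 and 4241 in the authors' deposited table. By the authors' edgeR test the window at 12081 had the smallest p of all 5184 windows, 0.00051, with an adjusted p of 1. Adjusted over the 188 rRNA windows alone it was 0.0791 by the authors' edgeR test, and 3 rRNA windows were below 0.1. No site was called on the 3 annotated 45S units of chromosome 21 in any of the 6 libraries, and rDNA on scaffolds was not analysed here. Whether the 2 knockouts differ from each other at these windows was not tested.

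**Figure D1:**
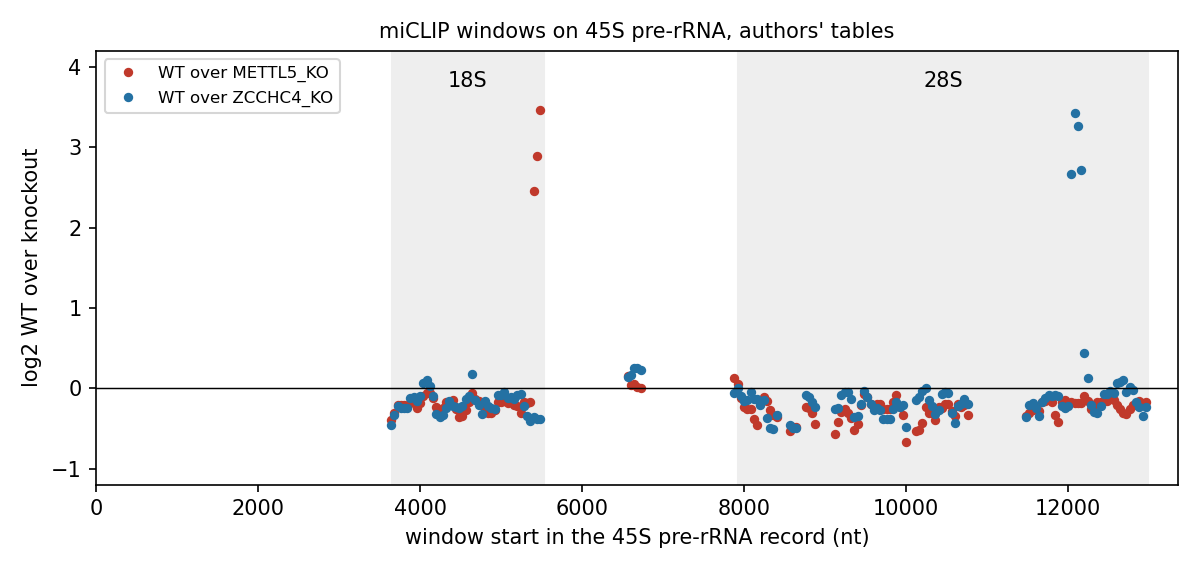
Log2 WT over knockout (vertical axis) of each window on the 45S pre-rRNA record by its start in nt (horizontal axis), from the authors' tables, red for the METTL5 knockout and blue for the ZCCHC4 knockout. Shaded spans are 18S and 28S. The METTL5 knockout stands apart at the end of 18S, up to 3.47, and the ZCCHC4 knockout in 28S, up to 3.43.

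Outside rRNA, the authors' deposited tables cover 4996 windows on 526 transcripts that carry Ensembl identifiers, which the files do not pair with gene names. No window passed an adjusted p of 0.05 by the authors' edgeR test in either table. Over all 5184 windows, rRNA included, at an unadjusted p under 0.05 the authors' deposited table for METTL5 held 34 windows, 15 lower and 19 higher in the knockout, and that for ZCCHC4 held 82, 37 lower and 45 higher. A uniform p would give 259.2 windows, and p was exactly 1 in 2183 and 1991 windows. Of the 15 and 37 windows that were lower, 4 were in both, where independent lists would share 0.107 and unchanged groups simulated against the same WT libraries shared a mean of 1.32 and at most 6 over 200 simulations. Of the 19 and 45 that were higher, 0 were in both, against 0.165 for independent lists and a simulated mean of 2.62. Neighbouring windows share tags, which the simulation leaves out. Among the 4 were the windows of ENST00000467568 at 721, 761 and 801, with log2 WT over METTL5 knockout of 2.06, 2.04 and 1.94 and log2 WT over ZCCHC4 knockout of 2.33, 2.61 and 2.95 in the authors' deposited tables. ENST00000396634 at 321 had a log2 of -2.21, higher in the METTL5 knockout, and ENST00000374677 at 561 had -2.75, higher in the ZCCHC4 knockout, in the authors' deposited tables. Across windows, which are not independent replicates, the log2 values of the 2 tables had a Pearson correlation of 0.477, a Spearman correlation of 0.457 and a covariance of 0.333. Both tables use the same WT libraries. Unchanged groups simulated against shared controls gave a correlation of 0.371 ± 0.0161 (SD over 200 simulations) and a covariance of 0.489 ± 0.0263. With equal depth in every library the simulated correlation was 0.498 and the covariance 0.619. The observed covariance lay below both simulated values. The simulated counts were Poisson, and their unequal depths came from the summed coverage over called sites, which is not library depth. Windows with more tags did not match so small a dispersion, so the simulations decide neither the correlation and covariance nor the overlap of windows.

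No site was called in the METTL5 gene in any library, so the lists do not check that knockout. In ZCCHC4, 1 site was called (chromosome 4, 25369176), in WT replicate 2 with 7 tags and in METTL5 knockout replicate 1 with 6 tags, and none in either ZCCHC4 knockout library. The coverage is close to the minimum of 4 tags in the lists. TRMT112, named in the series title as the stabiliser of METTL5, had 3 called positions, each in a single WT library. They had 42 and 40 tags in WT replicate 2 and 5 tags in WT replicate 1. Each had a C-to-T count of 2, the minimum in the lists, and none was called in both WT libraries. For the catalytic and partner subunits of the main mRNA m6A writer, METTL3 had 2 called positions and METTL14 had 5, each in a single library.

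The lists hold 24979 distinct positions. All are in the DRACH context of m6A because the lists were filtered to it, so the context is not a finding. The libraries had 1471 and 11760 sites in WT, 8924 and 6495 in the METTL5 knockout, and 2883 and 3859 in the ZCCHC4 knockout. The longest list was thus 7.99 times the shortest, and both belong to WT. Only 196 positions were called in all 6 libraries, and 18888 (75.6%) in a single one. FAT1, an atypical cadherin, had the most positions, 159, followed by AHNAK with 126, AKAP12, a scaffold of protein kinase A, with 97, the proliferation marker MKI67 with 84, and MALAT1, an abundant nuclear lncRNA, with 74. In the mean Jaccard index, no difference beyond the spread was seen between replicate pairs and pairs of different genotypes. The mean Jaccard index was 11.0% over the 3 replicate pairs and 10.5% over the 12 other pairs, and the difference of 0.460 percentage points was below the SD of 2.39 over the other pairs. Single replicate pairs differed. Among sites ranked above the middle of each list by C-to-T count, the METTL5 and ZCCHC4 knockout pairs had 19.7% and 19.6%. The other pairs ranged from 8.84% to 19.1%, and the WT pair had 7.40%. The unequal lengths of the WT lists limit their Jaccard index, and of the shorter list the WT pair shared 51.2%, the highest of the 15 pairs, the METTL5 knockout pair 30.0% and the ZCCHC4 knockout pair 25.8%, the lowest. With lists of equal length these were 29.1%, 39.2% and 30.0%, and WT replicate 2 shared 39.9% with METTL5 knockout replicate 2.

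**Figure D2:**
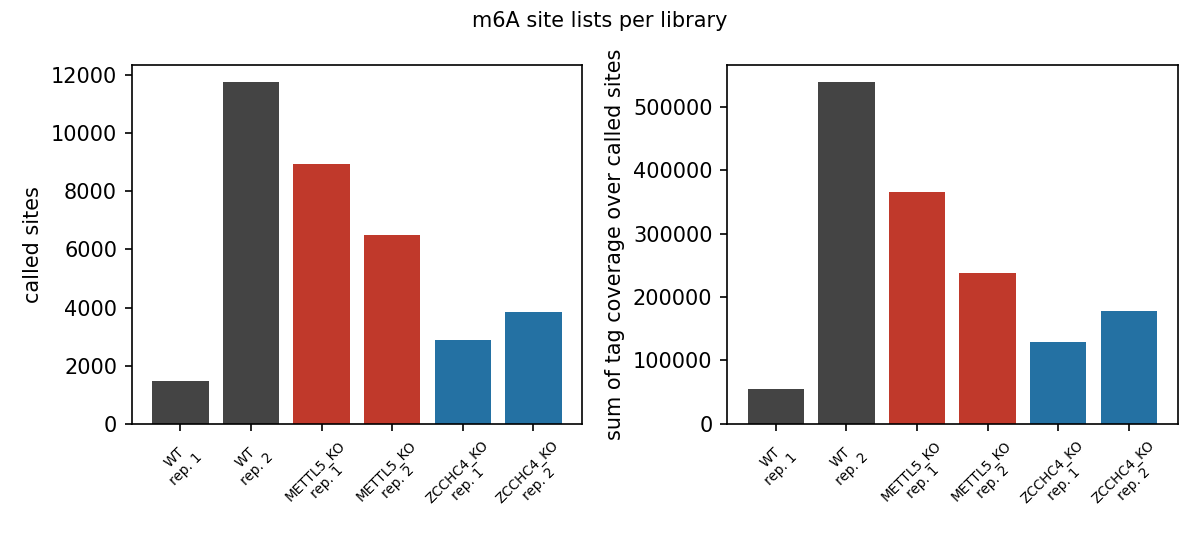
Number of called sites (left) and summed tag coverage over those sites (right) in each of the 6 libraries, 1 bar per library, grey for WT, red for METTL5 knockout and blue for ZCCHC4 knockout. WT replicate 1 has the fewest sites, 1471, and WT replicate 2 the most, 11760.

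Of the 753 sites called in both WT libraries, 155 were in neither METTL5 knockout library. The 10 with the highest coverage lay in mitochondrial ATP6 (position 8680) and COX2 (7905), in the nucleolar protein gene NCL, in the stress-induced DDIT4, in HSP90AB1, RPL11, MALAT1, PDE3A, YWHAE and RPL13A. Their C-to-T shares in WT ranged from 1.20% ± 0.191 (SD, n = 2) at ATP6 to 8.05% ± 2.76 (SD, n = 2) at MALAT1, with 4.96% ± 1.31 (SD, n = 2) at NCL. For ZCCHC4, 284 of the 753 were in neither knockout library, led by mitochondrial COX1 (6679), ATP6 (8680), ND4 (11752) and CYTB (15468), then AKAP12, a site at 38482150 on chromosome 2 in several genes, ND1, PDP1, GAPDH and DDIT4. The mean C-to-T share in WT was 1.44% at COX1, 1.20% at ATP6, 1.26% at ND4 and 1.65% at CYTB. These shares are close to the 1% minimum of the lists, so a small drop would remove the call. The other ways to pick 2 of the 4 libraries gave 61 to 1301 sites for METTL5 and 40 to 805 for ZCCHC4. These counts move with the lengths of the lists, so the range is no plain baseline. WT replicate 1 with a knockout library gave 86 and 61 for METTL5 and 40 and 47 for ZCCHC4. WT replicate 2 with a knockout library gave 1301 and 886 for METTL5 and 562 and 805 for ZCCHC4. Sites called in both knockout libraries and in neither WT library numbered 654 for METTL5 and 172 for ZCCHC4. With 2 libraries against 2 no exact permutation test can go below p = 0.333. Leaving out a library also relaxes the rule, and leaving out WT replicate 1 raised the counts to 8106 and 9617, leaving out WT replicate 2 gave 673 and 897, and leaving out METTL5 knockout replicate 1 or 2 gave 294 or 242.

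The 10 most covered sites called in all 6 libraries were all in mitochondrial 16S rRNA (RNR2), at 1865, 2240, 2314, 2322, 2357, 2368, 2375, 2708, 2766 and 3222. The most covered, at 2708, had a mean of 3444 tags and a C-to-T share of 2.08% ± 0.285 in WT, 1.69% ± 0.255 in the METTL5 knockout and 1.95% ± 0.405 in the ZCCHC4 knockout (SD, n = 2 each). Among nuclear sites, ACTG1, a cytoplasmic actin (chromosome 17, 81510684), had 13.5% ± 0.235, 11.5% ± 1.29 and 11.2% ± 2.32 in the same order (SD, n = 2 each), and EEF2, the translocation factor of translation (chromosome 19, 3976467), had 8.42% ± 1.07, 6.81% ± 0.448 and 7.18% ± 0.109 (SD, n = 2 each), with a mean coverage of 609.5 and 613 tags. Over the 163 nuclear sites called in all libraries the median C-to-T share was 8.37% ± 2.30 in WT, 7.80% ± 0.43 in the METTL5 knockout and 8.17% ± 0.561 in the ZCCHC4 knockout (SD, n = 2 each). These differences were below the spread between the WT libraries, and the exact permutation test gave p = 1 (two-sided, n = 2 each) for both knockouts. Over the 33 mitochondrial sites the median share in WT was 2.08% ± 0.121 (SD, n = 2). The share is bounded below at 1% by the lists, and every call needs at least 2 C-to-T tags. A site that lost its C-to-T tags in a knockout is left out here, so these medians cannot show such a loss. The nuclear median was 10% in WT replicate 1, the least covered library, and 6.75% in WT replicate 2.

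Of the DRACH 5-mers, GGACA, which was higher, and AGACA and TGACC, which were lower, did not overlap between WT and either knockout. GGACA made up 13.5% ± 0.385 of sites in WT, 14.8% ± 0.0256 in the METTL5 knockout and 15.4% ± 0.275 in the ZCCHC4 knockout (SD, n = 2 each), and GGACT 13.0% ± 0.366, 12.8% ± 0.75 and 14.0% ± 0.283 (SD, n = 2 each). Of the 18 5-mers, 6 had non-overlapping values for METTL5 and 6 for ZCCHC4, and chance gives a share of 0.333 for 2 against 2. Between single libraries, Fisher's exact test with adjustment over the 18 5-mers passed 0.05 for 1 5-mer each in 3 of the 15 pairs and in none of the 3 replicate pairs. The 3 pairs set WT replicate 2 against ZCCHC4 knockout replicate 1 (GAACA) and replicate 2 (AAACA), and METTL5 knockout replicate 2 against ZCCHC4 knockout replicate 1 (GAACA), which compares libraries and not genotypes. Nuclear protein-coding genes held 88.9% ± 2.89 of sites in WT, 91.2% ± 0.616 in the METTL5 knockout and 89.6% ± 1.03 in the ZCCHC4 knockout (SD, n = 2 each). Of these, 46.0% ± 1.79, 45.8% ± 0.561 and 46.0% ± 0.183 lay in the last 10% of the gene interval (SD, n = 2 each), and the exact permutation test gave p = 1 (two-sided) for both knockouts. Exons and UTRs were not analysed here.

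Tag coverage was then compared at the sites called in all 4 libraries of a comparison, a test added after the data had been examined. It measures how many tags cover a site, which moves with RNA level as well as methylation. In the METTL5 knockout, 6 of 372 sites passed an adjusted p of 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). ACTB, the cytoplasmic beta-actin, rose at both sites that passed, by a log2 of 0.92 (SE 0.189, adjusted p = 0.0362 by edgeR) at 5527532 on chromosome 7 and of 0.79 (SE 0.19) at 5527742. The ribosomal protein genes RPL13A and RPSA fell, RPL13A with log2 values of -0.85 and -0.90 at 49492116 and 49492074 on chromosome 19 and RPSA with -0.79 at 39411963 on chromosome 3. TRIB3, a pseudokinase of the stress response, had a log2 of -1.08 (SE 0.25, adjusted p = 0.0372 by edgeR) at 396965 on chromosome 20. Of 16 ribosomal protein sites in 11 genes, 0 were higher and 3 lower, and 6 passed when adjusted over the list alone. The list's camera test was lower with an adjusted p of 0.000543 at the preset correlation, and the adjusted p was 0.464 with an estimated correlation. Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.2. The 6 sites were 2 higher and 4 lower, against 4 and 5 with DESeq2's size factors, 7 and 6 with library totals, and 7 and 5 with scaling from nuclear sites, and all 6 passed under each of these scalings. No more than 1 site passed when any of the 4 libraries was left out, none of the 6 among them, and 0 passed with DESeq2's Wald test, while 58 had an unadjusted p under 0.05 by edgeR.

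In the ZCCHC4 knockout, 42 of 245 sites passed, 24 higher and 18 lower (edgeR's quasi-likelihood test, adjusted p under 0.05). Of 43 sites in mitochondrially encoded transcripts, 18 rose and 0 fell. They lay in the respiratory chain genes ND2, ND4, COX2 and CYTB and in RNR2. ND2 at 5135 had a log2 of 1.08 (SE 0.168, adjusted p = 0.000735 by edgeR), COX2 at 7782 of 1.06 (SE 0.171), ND4 at 10944 of 0.88 (SE 0.14) and CYTB at 15604 of 0.83 (SE 0.14). Of the nuclear sites, 6 rose and 18 fell, a balance set by the scaling: it was 20 and 12 with scaling from nuclear sites, and 8 and 5 when nuclear sites alone were tested. Of the 6 that rose, 3 were in TSC22D1, a leucine zipper regulator, up to a log2 of 1.04 (SE 0.222) at 44434582 on chromosome 13, and 1 each was in FAT1, RPL13A and SOX9, the last a transcription factor of intestinal progenitors with a log2 of 1.21 (SE 0.357, adjusted p = 0.0276 by edgeR). The site that fell most was in DDIT3, the stress-induced factor CHOP, with a log2 of -1.80 (SE 0.346, adjusted p = 0.00234 by edgeR) at 57516807 on chromosome 12. A site outside RefSeq genes at 202346374 on chromosome 2 had -1.77 (SE 0.302), TRIB3 at 396965 had -1.67 (SE 0.367), SIVA1 had -1.11 (SE 0.344), ATG12 had -1.06 (SE 0.354), the endoplasmic reticulum chaperone gene CALR had -1.03 (SE 0.219), and the 7SK RNA gene RN7SK had -1.01 and -0.93. CEBPB had -0.94, PYCR1, of proline synthesis, -0.89, RPL18 -0.85, and PDP1, a mitochondrial phosphatase gene, -0.84 at 1 of its 4 sites that passed.

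Of the lists, the 7 sites of the integrated stress and unfolded protein responses had 0 higher and 5 lower, in DDIT3, TRIB3, CALR and at 2 sites of HSPA5, and all 7 passed when adjusted over the list alone. Its camera test was lower with an adjusted p of 0.000116 at the preset correlation, and the adjusted p was 0.147 with an estimated correlation. Against no change, fry gave an adjusted p of 0.0226, under a scaling that left nuclear sites at a median log2 of -0.20. For the mitochondrially encoded transcripts camera was higher with an adjusted p of 1.19e-05, and the adjusted p was 0.147 with an estimated correlation. Against no change, fry gave an adjusted p of 0.00628, and 21 sites passed when adjusted over the list alone. The scaling sets the balance of directions. With library totals alone 18 sites were higher and 55 lower, and with scaling from nuclear sites alone 50 were higher and 12 lower, and under each of these scalings 36 of the 42 sites passed. The median log2 over all sites was -0.06 with the main scaling, -0.24 with library totals and 0.13 with scaling from nuclear sites. No site passed by edgeR when either ZCCHC4 knockout library was left out, which leaves 1 library in that group, and DESeq2's Wald test on all 4 libraries passed 23 sites.

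**Figure D3:**
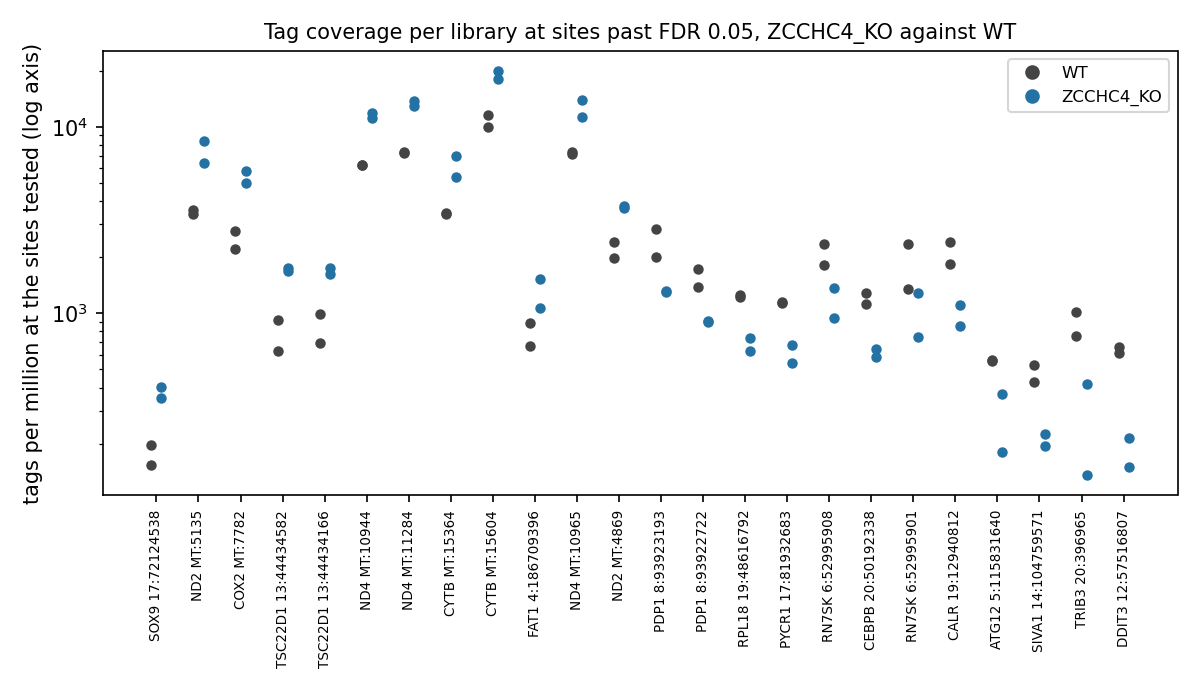
Tag coverage in CPM over the tested sites (vertical log axis) for the 12 most raised and 12 most lowered sites in named genes past an adjusted p of 0.05, ordered by log2 fold change, with 1 point per library, grey for WT and blue for ZCCHC4 knockout. In each of the 24 sites both knockout libraries lie on the same side of both WT libraries.

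Few sites of the remaining lists passed. For METTL5, 2 of 23 sites in transcripts with well known m6A passed, both in ACTB and higher. Of 13 stress response sites 1, in TRIB3, was lower. Adjusted over the list alone, 4 and 1 passed. The stress response list had a median log2 of -0.39 in this knockout too. Its camera adjusted p was 0.0791 at the preset correlation and 0.464 with an estimated one. Both knockouts were compared with the same WT libraries. By edgeR over all sites no site passed among the 40 of mitochondrially encoded transcripts, 15 of translation factors, 9 of immediate early genes, 6 of WNT and epithelial genes, 5 of histone genes, 5 of abundant lncRNAs, 3 of p53 targets, 2 of ribosome biogenesis factors, 2 of cell cycle genes and 1 of m6A readers and erasers, and adjusted over the list alone 2 lncRNA sites, in MALAT1, and 1 cell cycle site passed. For ZCCHC4, the p53 target GDF15 was lower at its 1 site, with a log2 of -0.80 (SE 0.164), and both sites of small nuclear and 7SK RNAs were lower, in RN7SK. Of 9 WNT and epithelial sites 1 was higher, in SOX9, and of 11 ribosomal protein sites 1 was higher, in RPL13A, and 1 lower, in RPL18, with 1 and 4 passing when adjusted over the list alone. By edgeR over all sites no site passed among the 20 in transcripts with well known m6A, 12 of translation factors, 9 of immediate early genes, 5 of abundant lncRNAs, 4 of histone genes, 2 of ribosome biogenesis factors, 1 of cell cycle genes and 1 of m6A readers and erasers, of which the cell cycle site, in MCM5, passed when adjusted over the list alone. The median log2 and the camera direction differed in sign for translation factors in both knockouts (medians -0.11 and -0.22), and for WNT and epithelial genes (-0.02) and well known m6A transcripts (-0.12) in the METTL5 knockout, each with a camera adjusted p above 0.05. The m6A writers had 0 sites in either test, and small nuclear and 7SK RNAs had 0 in that for METTL5. Markers of fibroblasts, endothelium and blood cells had 0 called sites in any library.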

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

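The tests of rRNA content and of chance among windows, and all tests of tag coverage, were chosen after the results had been seen.

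The lower signal at the end of 18S in the METTL5 knockout and in 28S in the ZCCHC4 knockout lay outside the range of the other windows of the 45S record. Less rRNA in the knockout libraries would lower the other 45S windows too, but their median log2 WT over knockout was -0.21 for METTL5 and -0.18 for ZCCHC4, while the named windows all lay above 2. Chance among many windows cannot be told apart from an effect, since the smallest p adjusted over the rRNA windows was 0.319 for METTL5 and 0.0791 for ZCCHC4 and no independent count is at hand. A loss of methylation by the deleted enzyme is consistent with the position of each block in the rRNA that the enzyme is known to act on, and stays a hypothesis.

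If low depth raised the mitochondrial share and so gave the higher coverage of mitochondrial sites in the ZCCHC4 knockout, WT replicate 1, the least covered library, would reach that knockout. At the sites called in all 6 libraries its share was 64.9%, against 68.3% in WT replicate 2. The ZCCHC4 knockout libraries had 72.8% and 72.3%. These sites had to be called in WT replicate 1, which favours nuclear sites that were high there and can lower its mitochondrial share. The comparison therefore cannot decide on depth. Over all called sites the mitochondrial share was 52.2% in WT replicate 1 and 26.5% in WT replicate 2. In the ZCCHC4 knockout libraries it was 55.3% and 51.2%. That sum moves with which sites were called, and depth is not excluded. With library totals 15 mitochondrial sites were higher, and the median log2 was 0.20 over mitochondrial and -0.37 over nuclear sites. With scaling from nuclear sites alone 30 mitochondrial sites were higher. That scaling raised the nuclear median from -0.20 to -0.02, so it favoured more such calls and could not test the explanation. The 2 classes stayed apart under each scaling, but scaling cannot tell a mitochondrial rise from a nuclear fall. A difference in RNA preparation or in clones, or an effect of the knockout on mitochondrial transcripts, stays open and untested.

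Sites called in both WT libraries and in no knockout library could come from calls near the calling floor. Among the 155 sites not called in the METTL5 knockout, 35.5% had a C-to-T count of 2 in both WT libraries, against 7.53% of the other 598, a difference of 27.96 percentage points (Fisher's exact test across sites, p = 1.23e-16). For ZCCHC4 it was 25.7% of 284 against 5.76% of 469, a difference of 19.9 percentage points (Fisher's exact test across sites, p = 2.13e-14). Both fit calls lost near the floor, which does not exclude that some of these sites depend on an enzyme.

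Tag coverage differed directly between the 2 knockouts at 58 of the 196 sites called in all 6 libraries (edgeR, adjusted p under 0.05). Of these, 31 were higher and 27 lower in the ZCCHC4 knockout. The higher sites included mitochondrial ones in CYTB, ND2, ND4, COX1, COX2 and RNR2, with a log2 of 0.89 at CYTB 15604. The lower sites were not mitochondrial. Other scalings were not run for this comparison. Outside the chromosomes, sites with no call in WT were called on the scaffold KI270733.1 at 124753 with 25 tags in METTL5 knockout replicate 1 and at 168888 with 24 tags in METTL5 knockout replicate 2, and on GL000219.1 at 57363 with 4 tags in METTL5 knockout replicate 1.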

How the results depend on the processing

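Of 99 alternatives to 16 results, 49 stayed within the limits set for no change and 50 moved, and 39 of the 99 were added after the data had been examined, namely every one for tag coverage and, for the authors' tables, the unadjusted p and the adjustment over the rRNA windows. Unless stated, the cause of a move was not tested.

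The ratio of the longest to the shortest site list was 5.17 when genes were counted. Sites of both WT libraries missing from the METTL5 knockout fell to 36 at or above the median coverage and 74 as genes, and ranged from 242 to 8106 when a library was left out. For ZCCHC4 the values were 90, 172 and 368 to 9617. Non-overlapping 5-mers numbered 11 to 14 for METTL5 and 10 to 14 for ZCCHC4 with a library left out, where fewer libraries make overlap rarer. The difference in sites in the last 10% of genes went from 0.0693 to -1.71 percentage points for ZCCHC4 with lists of equal length, past the spread of 1.27. In the authors' tables an unadjusted p under 0.05 gave 34 and 82 windows, and an adjusted p under 0.1 over the rRNA windows gave 3 for ZCCHC4. The correlation of the tables was 0.534 over windows with an unadjusted p under 0.05 in either. Lists with a site past the threshold rose from 3 to 5 for METTL5 when adjusted over the list alone.

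For tag coverage in METTL5 the 6 calls became 13 with library totals, 12 with scaling from nuclear sites, 12 with nuclear sites only, 0 with DESeq2's Wald test, 0 at 0.01, 11 at 0.1, 58 at an unadjusted p under 0.05, 1 with a log2 of at least 1, 10 with all 6 libraries in one fit and 0 to 1 with a library left out. For ZCCHC4 the 42 calls became 73 with library totals, 13 (8 higher, 5 lower) with nuclear sites only, 23 with DESeq2's Wald test, 18 at 0.01, 67 at 0.1, 89 at an unadjusted p under 0.05, 11 with a log2 of at least 1 and 0 to 56 with a library left out; a group left with 1 library is assumed to vary like the other.

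The replicate numbers are not stated to pair libraries. With the replicate number as a block, 0 sites passed for METTL5 and 22 for ZCCHC4. The deviations of same-numbered libraries had a correlation across sites of -0.12 for METTL5 and 0.0425 for ZCCHC4. With crossed numbers as the block 16 sites passed for METTL5. Crossing was tried for METTL5 alone, because its correlation was negative. That pairing was thus chosen from the same data, and the 16 calls do not show that it is real.

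The planned count tests, blocks and left-out libraries for the authors' tables were not run, because the tables hold no counts. Each comparison of site lists that needs both WT libraries is bounded by the 1471 sites of the shorter WT list, and why that list is short was not tested.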

Other observations

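Other transcripts differed between the 2 knockouts directly, at the sites called in all 6 libraries. SLC7A5, a large neutral amino acid transporter, had lower coverage in the ZCCHC4 than in the METTL5 knockout, with a log2 of -0.97 at 87831362 on chromosome 16 (edgeR adjusted p = 0.00231), and its partner SLC3A2 had -0.81 at 62888504 on chromosome 11 (edgeR adjusted p = 0.0107). TPT1 had 0.64 at 45337260 on chromosome 13 (edgeR adjusted p = 0.00249) and 0.18 at 45337045 (edgeR adjusted p = 0.524), and MALAT1 had 1.04 at 65500805 on chromosome 11 (edgeR adjusted p = 0.00434). These genes were chosen after their values were seen, and neither SLC7A5 nor SLC3A2 passed against WT at these sites in either knockout.

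The log2 changes of the 2 knockouts against WT at these 196 sites had a correlation of 0.304 across sites, where unchanged groups against the same WT libraries gave 0.561 ± 0.0543 (SD over 100 simulations). The covariance was 0.0533 against a simulated 0.0341 ± 0.00535. Part of any likeness comes from the shared WT libraries, which were not split.

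The 2 calls on KI270733.1 lay 44135 nt apart and had the same 5-mer, GGACC.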
